A study of Mus musculus with 12 samples.

How the data were processed

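Stranded poly(A) RNA libraries (TruSeq Stranded mRNA) were made from gastrocnemius muscle RNA and sequenced on an Illumina MiSeq, per the labels' protocols. The labels name 12 libraries in 4 groups of 3, from 2 genotypes and 2 treatments. RNA with an integrity number above the submitters' limit was used, per the labels' protocols. Reads were aligned with TopHat and counted per gene with featureCounts on the mm10 build, per the submitters' processing notes. The versions of both tools, the gene annotation and whether counting used strand are not given in the sources used here.

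The table the authors deposited holds 23420 gene rows, of which 7195 are at 0 in all 12 libraries. Per the file headers, the 12 library columns are normalised, and the authors deposited them as a signal in units of normalised counts. Within each library every value was a whole multiple of a single step, so the columns are gene counts divided by 1 factor per library. Division by that step gave whole reads for 100% of values in every library, within a tolerance of 1e-06 reads. For cARKO_Sham replicate 2 the step was 1.00 normalised counts, so close to 1 that an automatic test for whole reads could not separate it from rounding. The tool behind the authors' factors is not given in the sources used here. The 4 columns of group means are the authors' own means and were not used. The p-value and q-value columns come from a test of the authors, who deposited them without the groups it compared, and they are quoted only as the authors' values. The authors' rank and 0 or 1 call per gene in the deposited table, listed there as other values, were used for counts only. A further 2 columns were empty. In 27 rows the gene name had been turned into a date, and 2 names occurred more than once, so those genes cannot be named.

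The depth was 1171070 to 1500750 reads on genes per library, and 1 read was worth 0.907 to 1.17 normalised counts. A gene with few reads therefore carries a large counting error, and small changes of weakly expressed genes were not detectable at this depth. Intervals on ratios of reads are exact 95% Poisson intervals and cover counting error only.

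Groups were taken from the library titles. The values were analysed as log2(normalised count + 1), in limma 3.58.1 under R 4.3.3, for the 8239 genes with a mean of at least 10 normalised counts over the 12 libraries. These genes hold 98.5% of the reads. A single model with 4 group means was fitted to all libraries (lmFit, then eBayes with a mean-variance trend), and tests were two-sided with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. All fold changes are on the log2(normalised count + 1) scale, which understates the change of weakly expressed genes. The 5 comparisons were DHT against sham in control mice, DHT against sham in cARKO mice, cARKO against control in sham-operated mice, cARKO against control in DHT-treated mice, and the difference between the DHT effects of the genotypes (the interaction). Nothing in the labels states that each library came from a different mouse, so p-values measure the spread between these libraries and no more.

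Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over 23 lists. Of 24 lists fixed, the list of blood cell markers was not testable because its haemoglobin genes are listed at 0 or missing, and it is not reported further. The other lists were polyamine metabolism, androgen-responsive genes, steroid receptors and androgen metabolism, fast fibre sarcomere, slow and oxidative fibre sarcomere, excitation-contraction coupling, atrophy and ubiquitin ligases, growth factor and IGF signalling, myogenic and regeneration genes, neuromuscular junction and denervation, glycolysis and glycogen, fatty acid oxidation, oxidative phosphorylation, amino acid and integrated stress response, circadian clock, immediate early and heat shock genes, interferon response, and markers of extracellular matrix and fibroblasts, endothelium, adipocytes, macrophages and leukocytes, nerve and Schwann cells, and smooth muscle and pericytes. The androgen-responsive list shares Smox and Odc1 with the polyamine list. Amd1, Amd2, Oaz1 and Nkx3-1 are listed at 0 in every library. List scores are means over members of the log2 deviation from each gene's mean.

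The genes to be named, the lists, the groups, the tests and the settings to be varied were fixed before the data were examined. In each comparison the named genes are the 12 higher and the 12 lower called genes of largest fold change whose groups did not overlap, with Ar, Mylk4 (a gene known from the study) and the polyamine genes in every comparison. Up to 4 members of each further list were taken by smallest p where the set or a member was called. For cell type marker lists up to 2 members were fixed, but up to 4 were taken where the set or a member was called. For the interaction the 12 largest differences in each direction were taken among the called genes.

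The targeted gene Ar was tested by an exact two-sided permutation of the 6 cARKO against the 6 Control libraries. The overlap of calls in 2 comparisons that share libraries was set beside 50 simulations without effect. On data simulated from the real means with 200 changed genes, limma recovered, for DHT in control over 8244 genes, 24.6% of 1.5-fold, 75.4% of 2-fold and 100% of 4-fold changes, with 9.03% of calls false. For the interaction over 8230 simulated genes it recovered 7.46%, 36.9% and 89.2%, with 3.26% false. For DHT in cARKO over 8246 genes, 71.2% of 2-fold changes were recovered with 2.27% of calls false. For the sham genotype comparison over 8241 genes, 66.2% were recovered with 8.70% false, and for the DHT genotype comparison over 8254 genes, 67.2% with 6.71% false. Simulated shifted lists gave camera p between 3.2e-18 and 2.2e-11, and unchanged lists between 0.0167 and 0.808. The simulation did not include lists whose genes vary together. It therefore cannot show whether the preset correlation between genes is too low for the real lists.

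The settings varied were other pseudocounts, filters, scalings and variance models, array weights, a fit on the compared groups only, the replicate number as a block, an estimated correlation or fry for lists, and leaving out each library in turn. Count tests on the recovered reads, with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0, were added after seeing the data. edgeR called 300 genes for DHT in control, 16 for DHT in cARKO, 7 for genotype with sham, 357 for genotype with DHT and 96 for the interaction. Gene positions came from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, in which 7823 of the 8239 tested symbols (95.0%) and all 162 named symbols were found. Of the named genes, 59 overlap another gene on the opposite strand. Because the strand setting of the counting is not known, reads of such pairs may have been shared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.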

Results

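Messenger RNA was measured in the gastrocnemius, a calf muscle made mainly of fast fibres, of female C57BL/6 mice aged 13 weeks. cARKO mice lacked the androgen receptor in myofibres, through Cre recombinase expressed from the skeletal actin promoter HSA acting on a floxed receptor gene, and were compared with control littermates. Each genotype was sham-operated or carried a pellet of dihydrotestosterone (DHT), a potent androgen, for 4 weeks from 9 weeks of age. The 4 groups, Control_Sham, Control_DHT, cARKO_Sham and cARKO_DHT, held 3 libraries each. The libraries held 1171070 to 1500750 reads on genes, and 12638 to 13353 genes had at least 1 read. Myh4, the heavy chain of the fastest myosin, was the most abundant gene in all 12 libraries. It took 6.34% of the reads in Control_DHT replicate 2 and 7.16% to 8.26% in the others. Counts of the same-group pairs that include Control_DHT replicate 2 differed by 4.22 and 5.04 times sampling noise (chi-square per degree of freedom), against 1.4 to 2.32 for all other same-group pairs. No pair differed by less than sampling noise.

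The knocked-out gene was examined first. Ar, the androgen receptor (X:98148769–98323215, plus strand, 8 exons, mm10), had 4, 8 and 10 reads in the Control_Sham libraries and 13, 9 and 17 in the Control_DHT libraries. The cARKO_Sham libraries had 0 reads each, and the cARKO_DHT libraries had 1, 0 and 0. The 6 Control libraries held 61 reads and the 6 cARKO libraries 1, a ratio of 65.8 after correction for depth (95% counting interval 11.4–2640). The mean was 10.6 ± 4.56 normalised counts in Control and 0.153 ± 0.375 in cARKO (SD, n = 6), with an exact two-sided permutation p of 0.0021645, the smallest that 924 permutations can give. The exon removed by Cre is not given in the sources used here, and reads were counted over the whole gene. With so few reads, Ar fell below the level required for the test across genes.

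The first comparison asks which genes respond to DHT in muscle that has the receptor. In control mice DHT raised Smox and Odc1, genes of polyamine metabolism, and the kinase gene Mylk4, and lowered the sarcomere genes Mybph and Actc1. Smox, spermine oxidase (2:131491496–131525922), rose from 163 ± 21.7 to 704 ± 86.8 normalised counts, and Odc1, ornithine decarboxylase, the rate-limiting enzyme of polyamine synthesis (12:17544794–17551505), rose from 82.1 ± 7.67 to 354 ± 102 (SD, n = 3; limma, adjusted p = 6.8e-07 and 1.1e-06). Mylk4, a myosin light chain kinase family member (13:32700834–32783954), rose from 1741 ± 275 to 4650 ± 769 (limma, adjusted p = 7.7e-06). Mybph, myosin binding protein H (1:134193448–134201232), fell from 616 ± 101 to 42.3 ± 30.6, and Actc1, the cardiac alpha-actin also made in developing skeletal muscle (2:114047282–114053548), fell from 1368 ± 378 to 123 ± 73.0 (limma, adjusted p = 6.8e-07 and 2.1e-06).

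Altogether 297 of 8239 genes were called by limma, 179 higher and 118 lower with DHT, against 161 and 129 with median-of-ratios size factors and 142 and 119 with quantile normalisation. The largest rise was that of C7, a complement component (15:4988762–5063740), from 2 reads to 109 over the 3 libraries of each group (ratio 51.0, counting interval 13.8–426). Large rises were also seen for Slc30a2, a zinc transporter (log2 fold change 3.28), Slc2a3, the glucose transporter GLUT3 (3.17), Slc25a30, a mitochondrial carrier (3.05; 14:75760117–75787037), the transcription factor gene Tfcp2l1 (2.81) and Cdk19, a kinase of the Mediator complex (2.66; 10:40339564–40483818). Among these genes the adjusted p in limma lay between 1.1e-07 for Cdk19 and 2.3e-04 for Slc30a2. Nek6 (2.33), the scavenger receptor gene Stab2 (2.29), Hp, haptoglobin (2.26), the potassium channel gene Kcng4 (2.19) and Spns2, a sphingosine-1-phosphate transporter (2.13), rose as well. Large falls were those of Adora1, the adenosine A1 receptor (−3.77), Casr, the calcium-sensing receptor (−2.18), Lrtm1 (−1.78), Aebp1, a collagen-binding matrix protein (−1.73; 11:5861947–5872088), Klf15, a transcription factor induced by glucocorticoids (−1.59), and Klhl33 (−1.52). Adora1 (1:134199223–134235431) overlaps Mybph on the opposite strand, so its reads are uncertain. Fgfbp1 (−2.75), Kera (−1.81), Slc25a34 (−1.65), Gramd1b (−1.57) and Npnt (2.27) were also among the largest changes called.

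**Figure D1:**
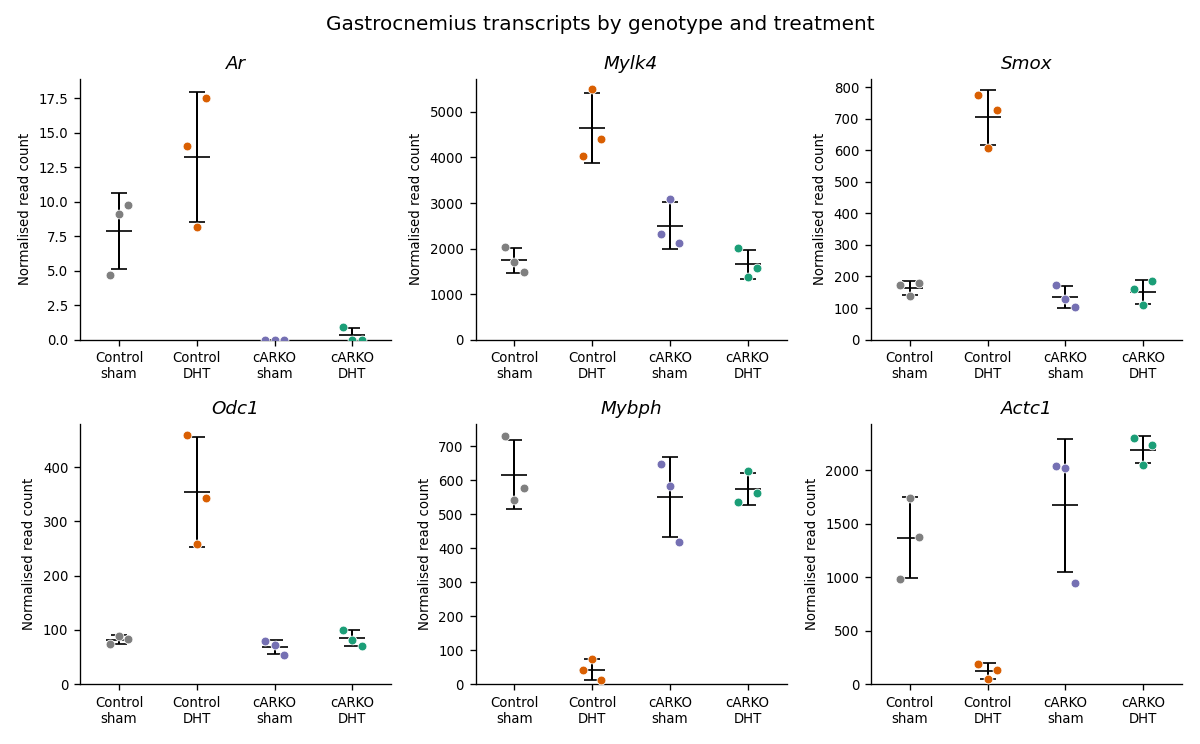
Normalised counts of Ar, Mylk4, Smox, Odc1, Mybph and Actc1 in each library (points; y axis, normalised counts) by group (x axis), with the mean and SD of 3 libraries as bars. In Control_DHT the 3 Smox values lie between 608 and 776 and the 3 Mybph values between 12.4 and 73.5, apart from every library of the other groups.

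By list, 2 of the 6 polyamine genes tested rose (Smox, Odc1) and 4 did when adjusted over the list alone, where Azin1, an antizyme inhibitor (log2 fold change 0.55), and Sms, spermine synthase (0.35), had an adjusted p of 0.022 each in limma. Oaz2 (0.10) and Sat1 (−0.15) were not called. The list was higher as a set (camera, adjusted p = 6.8e-04, and adjusted p = 0.195 with an estimated correlation). Of 13 genes of the slow and oxidative fibre sarcomere, 12 had negative fold changes, and the set was lower (median −0.67; camera, adjusted p = 0.0012, and adjusted p = 0.805 with an estimated correlation). Myl3, the slow myosin light chain (−0.85), was the 1 member called, and adjusted over the list alone 7 were lower and 1, Mb, myoglobin (0.39), was higher. The slow fibre score was 0.27 ± 0.243 in Control_Sham and −0.24 ± 0.243 in Control_DHT (SD, n = 3).

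Of 15 extracellular matrix and fibroblast genes, 4 fell (Col1a1 −1.04, Postn −1.33, Thbs4 −1.14, Fmod −1.22), and 7 did when adjusted over the list alone. The set was lower (median −0.40; camera, adjusted p = 2.5e-04, and adjusted p = 0.805 with an estimated correlation). The matrix score of Control_DHT replicate 2 was −0.968, against −0.45 ± 0.46 for its group (SD, n = 3). Without that library the set was not called (camera, adjusted p = 0.132). Of 6 macrophage and leukocyte genes, Lyz2 (0.91) and Csf1r (1.1) rose, 3 did when adjusted over the list alone, and the set was higher (camera, adjusted p = 0.021, and adjusted p = 0.553 with an estimated correlation). The call of this set was lost without Control_DHT replicate 1 (adjusted p = 0.0918) or replicate 2 (adjusted p = 0.151).

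Among lists not called as sets, Mstn, myostatin, an inhibitor of muscle growth (1:53061640–53068079), rose (0.88; limma, adjusted p = 5.6e-04), as did Musk, the agrin-responsive kinase of the neuromuscular junction (2.01; limma, adjusted p = 0.0034; 4:58285960–58374303), Hk2, hexokinase 2 (0.62), and Myod1, a myogenic transcription factor (1.62). Cacna1s, the voltage sensor of excitation-contraction coupling, fell (−0.54; limma, adjusted p = 4.7e-04), as did Pvalb, parvalbumin (−0.44), and Cdkn1a, the cell cycle inhibitor p21 (−1.20). The camera adjusted p was 0.0623 for both excitation-contraction coupling and nerve and Schwann cell markers (5 of 6 negative, median −0.71), 0.233 for both androgen-responsive and fast fibre genes, 0.508 for smooth muscle, 0.510 for oxidative phosphorylation and 0.539 for atrophy, fatty acid oxidation and circadian clock. It was 0.736 for the interferon response, 0.810 for glycolysis and adipocytes, 0.850 for steroid receptors, growth factors, neuromuscular junction and endothelium, 0.856 for myogenic genes and 0.863 for both stress response and immediate early genes.

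Of the 51 named genes called here, 25 were called in all 12 fits that left out 1 library each, and Slc2a3 in the 11 fits in which it was abundant enough for the test. Kera, Npnt and Fgfbp1 were abundant enough in only 7, 8 and 11 of the fits. Kera rested on 37 reads in Control_Sham and 9 in Control_DHT. Named genes that lost the call in 5 or more fits were Casq1, Csf1r, Ctsl, Eif4ebp1, Eng, Gadd45a, Gramd1b, Irs1, Ncoa1, Ppara, Sdhb and Slc38a2. Without Control_Sham replicate 1 the limma adjusted p was 0.0517 for Postn, 0.0868 for Thbs4, 0.179 for Fmod, 0.0846 for Myl3, 0.105 for Myod1, 0.105 for Npnt and 0.144 for Slc25a34. Without Control_Sham replicate 2 it was 0.0543 for Npnt, 0.0641 for both Pvalb and Slc25a34, 0.0764 for Myl3, 0.0840 for Fmod and 0.137 for Myod1. Without Control_Sham replicate 3 it was 0.0557 for Hk2, 0.0739 for Fgfbp1, 0.0887 for Lyz2 and 0.0921 for both Cdkn1a and Pvalb. Without Control_DHT replicate 1 it was 0.0508 for Slc25a34, 0.0933 for Myod1 and 0.104 for Fgfbp1, without replicate 2 it was 0.0532 for Myl3, 0.0912 for Slc25a34 and 0.118 for Fmod, and without replicate 3 it was 0.0582 for Myl3, 0.0612 for Myod1, 0.0667 for Kera and 0.0916 for Lyz2. The count of 297 fell to 182 without Control_Sham replicate 1 and to 191 without Control_Sham replicate 2.

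The second comparison asks what DHT does where myofibres lack the receptor. In cARKO muscle DHT changed few genes, and C7, Ace and C3 rose in both genotypes. C7 rose from 3 to 137 reads (ratio 42.7, counting interval 14.3–210), Ace, the angiotensin-converting enzyme (11:105967945–105989964), from 52.8 ± 8.55 to 141 ± 14.3 normalised counts, and C3, the central complement component (17:57203970–57228136), from 73.0 ± 6.77 to 152 ± 7.89 (SD, n = 3; limma, adjusted p = 1.9e-04, 0.0026 and 0.0051). Smox, Odc1 and Mylk4 were not called, with log2 fold changes of 0.16, 0.31 and −0.60 (limma, adjusted p = 0.90, 0.74 and 0.21). The polyamine genes Azin1 (0.18), Oaz2 (0.18), Sms (0.06) and Sat1 (−0.03) were not called either.

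In all, 11 genes were called by limma, 6 higher and 5 lower. Besides C7, Ace and C3, the collagen genes Col5a2 (log2 fold change 1.27) and Col3a1 (0.88) and Gsn, gelsolin (0.78), rose. Igfn1 (−2.42), the glutamine transporter gene Slc38a3 (−1.16), Fbp2, the muscle fructose-bisphosphatase (−1.07), Tbc1d1, a regulator of glucose transporter traffic (−0.87), and Car3, carbonic anhydrase 3 (−0.68; 3:14863512–14872523), fell. The fold changes of the 11 genes had the same sign in control mice, where C7 (4.60), Ace (1.09), C3 (0.71) and Car3 (−0.53) were called too. None of the 11 had a called difference between genotypes (limma), although 7 had an unadjusted p below 0.05. The median ratio of the control to the cARKO fold change was 0.439.

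**Figure D2:**
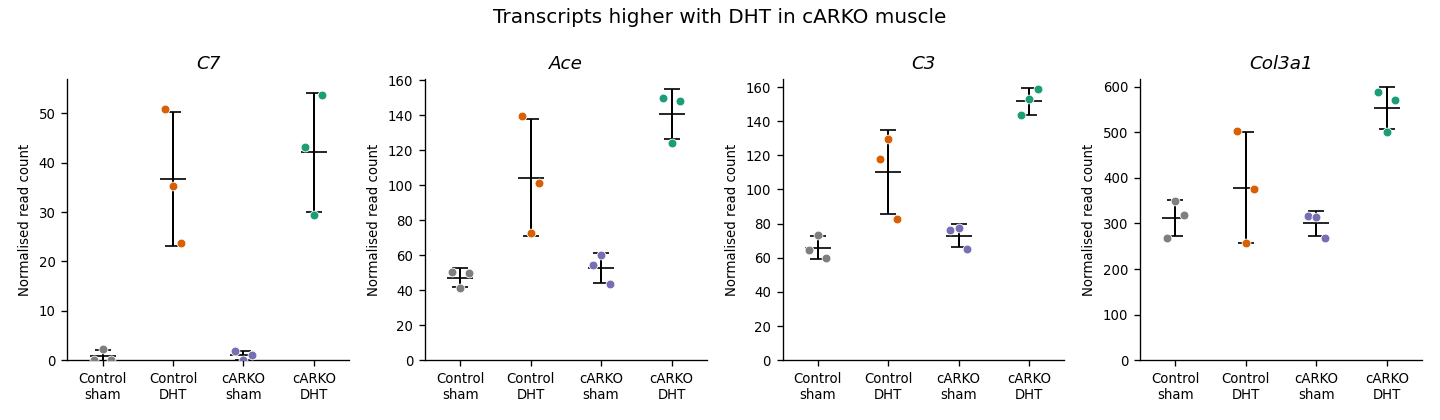
Normalised counts of C7, Ace, C3 and Col3a1 in each library (points; y axis, normalised counts) by group (x axis), with the mean and SD of 3 libraries as bars. In cARKO_DHT the 3 C7 values lie between 29.4 and 53.6, and in both sham groups none exceeds 2.28.

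By list, all 13 slow and oxidative fibre genes had negative fold changes in cARKO mice (median −0.61). The set was lower (camera, adjusted p = 8.6e-08, and adjusted p = 0.271 with an estimated correlation). No member was called over all genes, while 10 were lower when adjusted over the list alone, among them Myh7, the slow myosin heavy chain (−0.95), Casq2 (−0.83), Tnnt1, slow troponin T (−0.72), and Mb (−0.40). The score was 0.281 ± 0.303 in cARKO_Sham and −0.32 ± 0.33 in cARKO_DHT (SD, n = 3). Neuromuscular junction and denervation genes (12 tested, median −0.36) and nerve and Schwann cell genes (6 of 6 negative, median −0.50) were lower, and macrophage and leukocyte genes (6 of 6 positive, median 0.38) were higher (camera, adjusted p = 0.038 each). No member of these 3 sets was called, also when adjusted over the list alone, and each set lost its call in 5 of the 12 fits that left out 1 library. With an estimated correlation the adjusted p was 0.271, 0.636 and 0.468. Endothelial genes had a camera adjusted p of 0.063.

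C7, Ace and C3 were called in all 12 fits that left out 1 library. Col5a2 and Gsn lost the call without cARKO_Sham replicate 2 (limma, adjusted p = 0.0717 each), Gsn also without cARKO_DHT replicate 3 (0.0909), and the remaining 6 in 3 to 9 fits. The count of 11 was 3 without cARKO_Sham replicate 2, 5 and 6 without cARKO_DHT replicates 2 and 3, 23 without cARKO_Sham replicate 3 and 45 without Control_DHT replicate 2.

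The next question was whether the DHT response differed between genotypes. Many genes that DHT changed in control muscle responded less in cARKO muscle. The difference of log2 fold changes, control minus cARKO, was 2.02 for Mylk4, 1.94 for Smox and 1.75 for Odc1, and −4.22 for Mybph and −4.12 for Actc1 (limma, adjusted p = 4.4e-05, 3.5e-04, 1.0e-03, 1.2e-04 and 1.2e-04). In cARKO muscle Mybph was at 550 ± 118 and 575 ± 47.0 normalised counts without and with DHT, and Smox was at 135 ± 35.4 and 151 ± 39.3 (SD, n = 3).

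In all, 89 genes had a called difference (limma), 62 positive and 27 negative. With quantile normalisation the split was 58 and 41. Large positive differences were those of Slc25a30 (3.81), Tfcp2l1 (3.51), Spns2 (2.94), Tmem100 (2.55), Nek6 (2.47), Sbk2 (2.34), Cdk19 (2.31) and Serpinb6a (2.06), and large negative ones those of Adora1 (−3.61), Casr (−2.71), Ostn, the muscle hormone osteocrin (−2.48), Lrtm1 (−1.86), Aebp1 (−1.34), Klhl33 (−1.28), Itm2a (−1.26), Atp1b2 (−1.26) and Adhfe1 (−1.24). Among list members Hk2 (0.94) and Myh1, a fast myosin heavy chain (0.79), were called. All of these, like Mylk4, Smox, Odc1, Mybph and Actc1, were called in each of 12 fits that left out 1 library. The calls of Mss51 (2.97), Slc30a2 (3.14), Slc2a3 (2.66), Musk (2.50), Eif4ebp1 (1.34), Mb (0.79), Obsl1 (−1.34), Irs1 (−1.09) and Pvalb (−0.63) were lost in 5 or more such fits. The count of 89 was 55 without cARKO_Sham replicate 2 and 139 without Control_DHT replicate 2. The reads of Adora1 are uncertain here too, because it overlaps Mybph on the opposite strand.

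Of the 297 genes called for DHT in control mice, 83 had a called difference with the smaller response in cARKO. None had a called difference with a larger response in the same direction in cARKO. An opposite change in cARKO counts here as a smaller response, whatever its size. These genes were selected for their effect in control mice, which by itself favours a smaller response in cARKO. The fold change had the same sign in both genotypes for 161 genes (54.2%), and 4 were also called in cARKO. The median ratio of the cARKO to the control fold change was 0.0206 (interquartile range −0.155 to 0.268), and it was above 0.5 for 30 genes and below 0.25 for 217. The slope of the cARKO on the control fold change was 0.106, and 0.0582 without C7. Genes are not independent replicates, so no p-value is given for these summaries.

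**Figure D3:**
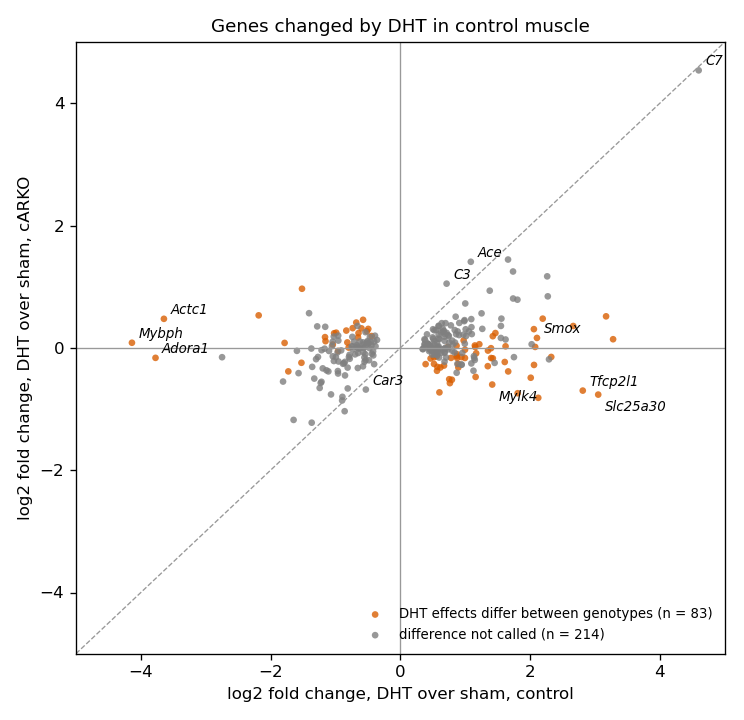
log2 fold change of DHT against sham in cARKO muscle (y axis) against that in control muscle (x axis) for the 297 genes called in control. Orange points are the 83 genes with a called difference between the genotypes and grey points the other 214, most points lie near 0 on the y axis, and C7 lies apart at 4.60 and 4.54.

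By list, the DHT effect was more positive in control than in cARKO mice for polyamine genes (camera, adjusted p = 0.0276, and adjusted p = 0.706 with an estimated correlation) and androgen-responsive genes (camera, adjusted p = 0.042, and adjusted p = 0.889 with an estimated correlation). In both lists the 2 members called were Smox and Odc1. Adjusted over the list alone, 3 androgen-responsive genes were called, the third being Fkbp5, a chaperone gene induced by steroid receptors (2.24; limma, adjusted p = 0.018 over the list alone and 0.17 over all genes). Matrix and fibroblast genes were negative for 14 of 15 members (camera, adjusted p = 3.12e-05, and adjusted p = 0.889 with an estimated correlation), with no member called and 1, Col1a1, when adjusted over the list alone. This set was still called without Control_DHT replicate 2 (adjusted p = 0.0199). The polyamine call was lost in 6 and the androgen-responsive call in 7 of the 12 fits that left out 1 library.

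The fourth comparison asks how cARKO muscle differs from control muscle when both carry DHT. Smox, Odc1 and Mylk4 were lower, and Mybph and Actc1 were higher in cARKO. The log2 fold change was −2.24 for Smox, −2.03 for Odc1 and −1.50 for Mylk4, and 4.36 for Actc1 and 4.05 for Mybph (limma, adjusted p = 2.4e-07, 9.8e-07, 3.6e-06, 2.1e-07 and 6.9e-07).

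Of 340 genes called by limma, 132 were higher and 208 lower in cARKO, against 157 and 168 with quantile normalisation. Among the lower genes were Mss51, a mitochondrial protein gene of muscle (−3.45), Slc30a2 (−3.17), Slc25a30 (−3.15), Slc2a3 (−3.10), Stab2 (−2.84), Musk (−2.65), Spns2 (−2.64), Odf3l2 (−2.64), Cdk19 (−2.47), Sbk2 (−2.41) and Tfcp2l1 (−2.30). Among the higher genes were Adora1 (3.70, again with uncertain reads), Casr (2.89), Golga7b (2.40), Lrtm1 (2.25), Tiam1 (1.92), Ostn (1.75), Arid5a (1.74), Cdkn1a (1.73), Ak4 (1.72) and Gamt, a creatine synthesis enzyme (1.71). Of 15 matrix and fibroblast genes all had positive fold changes, 5 were called (Col1a1 1.04, Postn 1.26, Thbs4 1.3 and Mmp2 0.80 among them) and 10 were when adjusted over the list alone. The set was higher (camera, adjusted p = 3.7e-08, and adjusted p = 0.50 with an estimated correlation) and was called without Control_DHT replicate 2 (adjusted p = 5.0e-04). Polyamine genes and androgen-responsive genes were lower (camera, adjusted p = 0.028 each, and adjusted p = 0.50 each with an estimated correlation), and Oaz2, an antizyme that restrains ornithine decarboxylase, was higher (0.43). Adjusted over the list alone, 3 polyamine genes were lower and 1 higher, and 3 androgen-responsive genes were lower. Mstn (−1.26), Eif4ebp1 (−1.03), Myh1 (−0.90), Hk2 (−0.69) and Mb (−0.69) were lower, and Pvalb (0.50), Ache, acetylcholinesterase (0.81), Klf15 (1.37) and Irs1 (0.84) were higher.

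Of the 297 genes that changed with DHT in control mice, 177 (59.6%) were also called here in the opposite direction, 109 higher with DHT and lower in cARKO and 68 the reverse, and none in the same direction. Independent lists would share 4.52 and 1.89 genes, a value that leaves out the shared Control_DHT libraries, and 50 simulations without effect gave an overlap of 0, a value that leaves out the effects. Neither is the overlap to be had from the shared libraries when both comparisons hold effects. These libraries are too few to split, so part of the overlap may come from them. For 79 genes, 56 higher and 23 lower with DHT, the difference of DHT effects was called as well.

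The call of the polyamine set was lost in 5 fits that left out 1 library and that of the androgen-responsive set without Control_DHT replicate 1 (adjusted p = 0.213) or cARKO_DHT replicate 3 (adjusted p = 0.104). Of the 45 named genes called here, 12 lost the call in at least 1 such fit. These were Arid5a, Casq1, Mmp2, Ndufs2 and Sdhb in 5 or more, and Ache, Ctsl, Irs1, Klf15, Oaz2, Odf3l2 and Slc38a2 in fewer. The limma adjusted p was 0.108 for Klf15 without cARKO_DHT replicate 1, 0.0963 for Oaz2 without cARKO_DHT replicate 2 and 0.0577 for Odf3l2 without Control_DHT replicate 3. The count of 340 was 214, 182 and 217 without cARKO_DHT replicates 1, 2 and 3 and 223 without Control_DHT replicate 3.

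The last comparison asks what the loss of the receptor does in sham-operated females. Few genes were called, and genes of the neuromuscular junction and of denervated muscle were higher in cARKO as a set. Chrna1, the alpha subunit of the muscle acetylcholine receptor (2:73563215–73580338), was higher (29.0 ± 5.40 to 71.3 ± 16.5 normalised counts, SD, n = 3; log2 fold change 1.26; limma, adjusted p = 0.035), and 11 of 12 list members had positive fold changes (median 0.40). The set was called with either correlation (camera, adjusted p = 1.6e-04, and adjusted p = 0.0375 with an estimated correlation), 1 member was called, and 2, Chrna1 and Ache (0.55), were higher when adjusted over the list alone. The neuromuscular junction score was −0.14 ± 0.111 in Control_Sham and 0.272 ± 0.122 in cARKO_Sham (SD, n = 3). With DHT the set was not called between genotypes (median 0.48; camera, adjusted p = 0.404). There 9 members were positive, and 4 were higher and 2 lower when adjusted over the list alone. The difference of DHT effects was not called for the set either (camera, adjusted p = 0.532), so no difference between the treatments was shown. No other list was called with sham, and those with the smallest p were the myogenic and regeneration genes (median 0.66), macrophage and leukocyte genes (0.44) and interferon response genes (0.38), each with a camera adjusted p of 0.072, and the fast fibre genes (−0.11; 0.114).

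limma called 7 genes. Tiam1, a Rac exchange factor (1.75; 16:89787111–90143769), Mpp3 (1.14), Ggnbp1 (0.98) and Chrna1 were higher, and 2310065F04Rik (−1.08), Dmd, dystrophin (−1.0; X:82948870–85206141), and Sorbs2, a Z-disc adaptor (−0.91; 8:45507788–45827906), were lower. All 7 had the same sign with DHT, and Tiam1, 2310065F04Rik, Dmd and Sorbs2 were called there too, in libraries not shared with this comparison. Independent lists would share 0.14 genes. That value leaves out that both comparisons use the same estimate of each gene's spread, taken over all 12 libraries. Mylk4 (0.52; limma, adjusted p = 0.37) and the polyamine genes Smox (−0.30), Odc1 (−0.28), Sms (−0.10), Azin1 (−0.08), Sat1 (0.10) and Oaz2 (0.35) were not called. A genotype effect averaged over both treatments was called for 81 genes counted as similar in both. Their effects had the same sign with sham and with DHT, but their sizes could differ. Among them were Mstn (−0.64 with sham, −1.26 with DHT) and Cdkn1a (0.87 and 1.73), both with the larger effect with DHT. That average includes the DHT libraries, but genes not called with sham were thus not shown to be equal there. Each of the 7 calls was lost in at least 3 fits that left out 1 library. The count was 0 without Control_Sham replicate 1 or cARKO_Sham replicate 2 (limma, with 615 and 473 genes at an unadjusted p below 0.05), 1 without Control_Sham replicate 3 or cARKO_Sham replicate 1, 2 without Control_Sham replicate 2, 3 without cARKO_DHT replicate 3 and 12 without Control_DHT replicate 2. edgeR gave 7 genes with all libraries, and 0 without cARKO_Sham replicate 2.

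**Figure D4:**
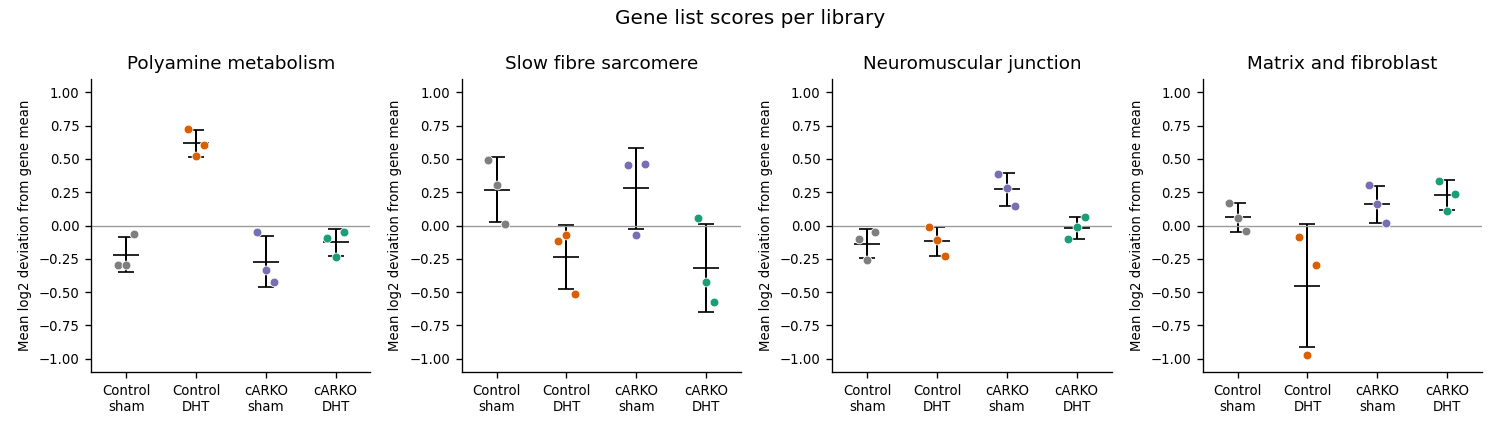
Scores of the polyamine, slow fibre, neuromuscular junction and matrix lists in each library (points; y axis, mean over list members of the log2 deviation from each gene's mean) by group (x axis), with the mean and SD of 3 libraries as bars. The polyamine score is highest in Control_DHT (0.616 ± 0.0991), the slow fibre score is lower in both DHT groups, and the matrix score of Control_DHT replicate 2 lies at −0.968.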

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

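The tests of residual receptor, fibroblasts, DHT action outside the myofibre receptor, uneven slow muscle, tendon and the singly called matrix genes were chosen only after the results were seen.

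A difference between the DHT effects of the genotypes (control minus cARKO, limma interaction) was called for 89 genes. Of 100 drawn splits of the treatments within each genotype, the real one included, none of the others gave as many, the highest being 86. The 11 other splits that kept the treatments of the control libraries gave 47 to 86 genes, and those that mixed them at most 5, as a DHT effect in control with little response in cARKO would give. With treatments assigned at random in both genotypes together, no other drawn split reached the real count, but not every split was drawn. The splits do not by themselves test a difference between the genotypes. For the other 4 comparisons the 10 splits of 6 libraries are too few for a share under 0.05, with real counts of 297, 11, 7 and 340 genes (DHT in control, DHT in cARKO, genotype with sham, genotype with DHT) and highest counts of another split of 0, 1, 5 and 0.

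The named genes with a more positive DHT effect in control than in cARKO were Slc25a30 (3.81), Tfcp2l1 (3.51), Slc30a2 (3.14), Mss51 (2.97), Spns2 (2.94), Slc2a3 (2.66), Tmem100 (2.55), Musk (2.50), Nek6 (2.47), Sbk2 (2.34), Cdk19 (2.31), Serpinb6a (2.06), Mylk4 (2.02), Smox (1.94), Odc1 (1.75), Eif4ebp1 (1.34), Hk2 (0.94), Mb (0.79) and Myh1 (0.79). Differences in the other direction were those of Mybph (−4.22), Actc1 (−4.12), Adora1 (−3.61, with reads uncertain as it overlaps Mybph), Casr (−2.71), Ostn (−2.48), Lrtm1 (−1.86), Aebp1 (−1.34), Obsl1 (−1.34), Klhl33 (−1.28), Atp1b2 (−1.26), Itm2a (−1.26), Adhfe1 (−1.24), Irs1 (−1.09) and Pvalb (−0.63). The same test called the polyamine list (camera, adjusted p = 0.0276), the androgen-responsive list (0.042) and the matrix list (3.12e-05), and none of these with an estimated correlation (adjusted p = 0.706, 0.889 and 0.889).

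The first pattern weighed is the set of 11 genes that changed with DHT in cARKO muscle. Receptor left in the myofibres could keep a common share of the whole control response. The tables argue against such a common share, since the median ratio over the 297 genes was 0.0206 (0.0129 to 0.0416 without 1 library). As another measure, 1 replicate number of each group was held out in turn and the genes were called without it. In the held-out libraries the ratio of the median cARKO response to the median control response was 0.0411, 0.0921 and 0.0748, over 178, 156 and 109 genes. Neither measure speaks for the 11 genes singly, so for them receptor left in the myofibres stays open. More fibroblasts are argued against only for C7. Its log2 fold change of 4.54 (4.11 or more without 1 library) lay far above all 26 fibroblast and matrix markers (highest 0.881, upper quartile 0.420). Ace, C3 and Col5a2 (1.05 or more) lay above the markers too, but were picked for their rise. Their lower 95% limits went down to 0.724, below the highest marker, and Col5a2 is itself a collagen gene. For them, and for the markers Col3a1 and Gsn, more fibroblasts cannot be told apart from a change of single genes. The median of the 26 markers was 0.24, with 22 above 0. Also open is an action of DHT that does not need the receptor of myofibres, since 11 of 11 genes moved the same way in control mice, with an interval of −1.42 to 1.54 for the difference of C7. Whether it would act through the receptor of other cells or through the whole animal cannot be read from these data, and 7 of the 11 differed between genotypes at an unadjusted p below 0.05.

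The second pattern is that slow fibre genes were lower with DHT in both genotypes, beside nerve and Schwann cell genes with a median of −0.71 in control (5 of 6 negative; camera, adjusted p = 0.0623) and −0.50 in cARKO (6 of 6; 0.038). The mean difference of the score was −0.551, against an SD within groups of 0.282. An uneven share of slow muscle between the dissected pieces cannot be told apart from an effect of DHT, since the exact permutation of treatments within genotypes, over 400 arrangements, gave p = 0.015 for this list alone and p = 0.24 against the highest of all 23 lists, from which it was picked after the results. Fewer slow fibres in the piece and lower expression per fibre cannot be told apart, because 6 slow fibre genes outside the list had a median of −0.21 (interquartile range −0.329 to −0.0252), against −0.652 for the list, and 4 of the 6 were below 0, while by genotype 4 of the 6 were above 0 in control (median 0.164, with Smpx called higher at 0.55; limma, adjusted p = 0.0027) and 5 below 0 in cARKO (median −0.287). No count of fibres was available here.

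The third pattern is that matrix genes were lower with DHT in control muscle. For the list, the call rests on Control_DHT replicate 2, without which its median went from −0.40 to −0.15 and its adjusted p to 0.132. For the 4 members called singly the tables argue against that library as the whole cause, since without it their median was −0.84, against −1.18 with it, and Col1a1, Postn and Thbs4 were still called (limma, adjusted p = 0.0204, 0.0256 and 0.0434) while Fmod was not (0.118). Less tendon in the Control_DHT pieces cannot be told apart from an effect of DHT, since 7 tendon genes lay 1.12 below 15 interstitial genes in median log2 fold change, but 3 of them (Kera, Fmod, Thbs4) had been seen to fall before the test was chosen, and the other 4, Col12a1 (−1.28), Chad (−0.49), Prg4 (−0.15) and Angptl7 (0.23), are too few (median difference −0.3). An effect of DHT on matrix genes through the myofibre receptor also stays open.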

How the results depend on the processing

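The edgeR and DESeq2 tests were chosen after the data were seen, and all other settings before. Of 276 alternatives of the main results, 205 kept the value within 1.5 times or 1 SD or kept the call, and 71 moved it. A reversal could be scored only for Ar, and none was seen there. The SD was used for the share of DHT effect kept in cARKO and was that of the same share over the fits that left out 1 library. The fit on the compared groups gave 178 genes for DHT in control, 35 for DHT in cARKO, 113 calls shared by DHT in control and genotype with DHT, and 0.03401 as the share of DHT effect kept in cARKO. Without a variance trend the 5 counts were 137, 1, 3, 168 and 35, with 84 shared calls and a share of 0.03354. A minimum mean 5 times higher gave 2 genes for genotype with sham, no filter gave a share of 0.03274, and array weights gave 32 genes for DHT in cARKO. edgeR gave a share of 0.009941 and DESeq2 17 genes for DHT in cARKO. edgeR without cARKO_Sham replicate 2 gave 7 genes for DHT in cARKO, 0 for genotype with sham (473 at an unadjusted p below 0.05 in limma) and 58 for the interaction, and without Control_DHT replicate 2 it gave 54, 13 and 149. With an estimated correlation 0 lists were called for DHT in control, DHT in cARKO, genotype with DHT and the interaction, and fry called 1, 0, 1 and 0. The cause was not tested for any of these.

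Leaving out 1 library gave 182 to 312 genes for DHT in control, 3 to 45 for DHT in cARKO, 0 to 12 for genotype with sham, 182 to 359 for genotype with DHT and 55 to 139 for the interaction. The lowest counts came without Control_Sham replicate 1, cARKO_Sham replicate 2, either of these, cARKO_DHT replicate 2, and cARKO_Sham replicate 2, and the highest for DHT in cARKO, genotype with sham and the interaction without Control_DHT replicate 2. The kept share ranged from 0.01288 to 0.04156, shared calls from 121 to 199 and the Ar difference from −3.46 to −3.12. Lists called ranged over 3–5, 1–4, 1–3, 1–3 and 1–3 in the same order. In each of these fits, as in the main fit, the spread was pooled over all groups, also where a group was left with 2 libraries. A library outside a comparison could therefore change its count. Control_DHT replicate 2 did so for DHT in cARKO, with 11 genes called with it and 45 without it.

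The replicate numbers were not taken to pair the libraries, because the labels do not say that a number marks a litter or a day and 3 of 18 same-number pairs, not all, had a correlation of deviations above 0.1 (range −0.063 to 0.169). As a hint from the data that libraries of a number may share something, 9 of 12 had their best partner under their own number, and the median was 0.078, against −0.030 for other numbers. With the replicate block the counts were 357, 31, 10, 406 and 121, the share was 0.03354, and no list lost its call.

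Of 3713 checks on the 147 called results of named genes, 3166 kept the call, 547 lost it and none reversed. Of 4275 checks on the 169 not called, 105 gained it and 37 changed sign. Of 225 checks on the 15 called lists, 161 kept the call and none turned. Ar had no fit on the compared groups or with a higher minimum, and the interaction had none on the compared groups. With 1171070 to 1500750 reads, 1.5-fold changes were mostly below reach in simulation (24.6% recovered for DHT in control).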

Other observations

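All 3 lists tested here were written only after their genes had been seen among the results, so their tests include genes that prompted them. A first hypothesis was that genes of the imprinted gene network, a group of growth-regulating genes expressed from the maternal or paternal allele, shift together with DHT in control muscle. Of 11 tested, 4 fell, namely Meg3 (log2 fold change −1.11), Rian (−1.23), Peg3 (−1.04) and Grb10 (−0.97), and 9 were below 0 (median −0.65). The set was lower (camera, adjusted p = 5.8e-07 over the 3 lists, and p = 0.0012 with an estimated correlation), a test that includes the 4 genes that prompted it. The members not called singly gave an adjusted p of 0.0487 (camera) and kept that call in 4 of the 12 fits that left out 1 library (highest 0.232), so a shift beyond the called members stays open. The set was higher in cARKO than in control with DHT (adjusted p = 1.3e-06) and not called for DHT in cARKO (0.46), and the difference of DHT effects was called (9.1e-05). Through which cells or receptor was not tested. Igf2 and Dcn also stand in the lists fixed earlier.

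Genes of branched-chain amino acid breakdown were lower with DHT in control muscle as a set (22 tested; camera, adjusted p = 0.016, and p = 0.0229 with an estimated correlation). The 4 members called were Bckdha (−0.50), Dbt (−0.71), Ivd (−0.45) and Mccc2 (−0.73). Over the members not called singly in the same comparison the adjusted p in camera was 0.505 for DHT in control and 0.0504 for genotype with DHT, so a shift of the pathway beyond its called members was not shown. The set was called for genotype with DHT (camera, adjusted p = 0.0062) and for the interaction (0.0191), where no member was called singly, and not for DHT in cARKO (0.599). Without Control_DHT replicate 3 the adjusted p for DHT in control was 0.0600. Proteasome subunits were tested as a further hypothesis because Psmd8 rose (1.15; limma, adjusted p = 3.8e-06). No other subunit was called for DHT in control (limma), and the set of 31 was not called for DHT in control (camera, adjusted p = 0.232). It was called for genotype with DHT (0.0499) and for the interaction (0.0377), in neither case with an estimated correlation (p = 0.378 and 0.352) or over the members not called singly (camera, adjusted p = 0.142 and 0.112).

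The authors marked 529 genes in their deposited table as called, and 459 of these were tested here. They include 368 of the 469 genes called here in any pairwise comparison. The authors' deposited table ranks Cdk19 (q = 8.9e-72) and Ttll7 (q = 5.3e-60) highest, and the groups that test compared are not stated. These 2 genes were chosen for their rank after the values were seen.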
